A study of Mus musculus with 32 samples.

How the data were processed

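Frontal cortex RNA was measured in 32 mice inoculated with gut microbiota from humans (12 mice), squirrel monkeys (8 mice) or macaques (12 mice). Libraries were made with a tag-based method (TagSeq), which sequences near the 3′ end of polyadenylated transcripts, and were read as single reads, per the labels' protocols. The authors deposited one table of raw counts per Ensembl gene with 23958 rows. The values used here are whole-number counts whose totals differ between mice. The build named in the submitters' processing notes is GRCm39. The aligner, the counting tool, the annotation release, the use of strand in counting and the handling of duplicate reads are not given in the sources used here. The series design speaks of 11359 detected genes without ribosomal genes, and that filter is not applied in the deposited table.

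The table also held 3 columns of counts that match no sample used here, and they entered no step. Gene symbols came from a table of gene names; 76 rows had no symbol there and held 0.031% of all counts. Transcript length, GC content, overlapping genes and copies of the last 300 bases of each transcript were taken from GENCODE release M21, which belongs to another build than the counts. For that reason no coordinates are given. A copy was counted where at least 100 bases aligned at 95% identity or more. Without stated strand use, reads of overlapping genes on opposite strands cannot be told apart, and values of such genes are uncertain.

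The total was 1035040 to 2089310 counts per mouse (median 1534710), so that 5 CPM (counts scaled to a common library total) correspond to about 7.67 counts in a mouse of median depth. The labels give no unit above the mouse other than the batch. Each of the 6 batches holds mice of 1 donor species (A and B human, C and D squirrel monkey, E and F macaque). The library names place all libraries on 1 plate, with human libraries in columns 1 and 2, squirrel monkey libraries in column 3 and macaque libraries in columns 4 and 5. Donor species, batch and plate column therefore cannot be separated by any fit. Chi-square per degree of freedom over the 160 pairs of mice of the same donor species ranged from 1.45 to 7.79, and 0 pairs held identical counts.

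Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the donor group (minimum count 10, minimum total 15), which left 12651 genes, and scaled with TMM factors (0.955 to 1.04). The quasi-likelihood test was fitted to all 32 mice with the donor group as the only term. The 4 comparisons were human against macaque, squirrel monkey against macaque, human against squirrel monkey, and the equally weighted mean of human and squirrel monkey against macaque. An F-test asked whether any group differed. A fit on the 6 batches gave the differences between batches of the same donor species. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The common biological coefficient of variation was 0.138. Fold changes are given as log2 with the standard error (SE). Levels are given as mean CPM ± SD over mice.

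Before the data were examined, 44 gene lists were written from general knowledge, none chosen on these samples, and 43 of them had at least 3 measured members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, and again with a correlation estimated per list. A list score is the mean over members of log2 CPM after subtracting each gene's mean over the 32 mice. Permutation tests were two-sided, exact where a group held fewer than 10 mice and by resampling otherwise. Score tests of the combined comparison pooled its 20 human and squirrel monkey mice, whereas the fits weighted the groups equally. The lists whose scores were tested were chosen after the list results were seen.

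The rule for named genes was also fixed in advance. In each comparison it takes the 8 higher and the 8 lower genes of largest fold change among those past the threshold, with a mean of at least 5 CPM, and with every batch of one side above or below every batch of the other. Unnamed gene models were passed over: 40 in human against macaque, 2 in squirrel monkey against macaque, 0 in human against squirrel monkey and 24 in the combined comparison. From each list described, up to 4 members of smallest p are named. Between batches, the rule takes the 3 higher and 3 lower genes of smallest p. Some genes that these rules take are not reported here.

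The test was tried on simulated counts for the 12651 genes. In human against macaque it recovered 20.9% of genes changed 1.25-fold, 68.7% of those changed 1.5-fold and 95.5% of those changed 2-fold. In squirrel monkey against macaque the shares were 19.4%, 71.6% and 93.9%. False calls numbered 7 (5.38% of calls) and 4 (3.15%).

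Alternatives planned in advance were DESeq2 size factors, library totals without further scaling, other filters, DESeq2 1.42.0, limma voom with sample weights, batch as fixed levels, batch as a random effect, counts summed per batch, fits on the groups compared alone, library total as a covariate, robust empirical Bayes, a threshold of 0.01, leaving out each batch and leaving out each mouse. Chosen after seeing the data were fits without ribosomal protein genes, with a myelin score, a ribosomal protein score or a receptor gene score as a covariate, and without the 5 mice of highest myelin score. For gene lists, library total as a covariate was also added after seeing the data, as was camera on ranked edgeR statistics, without and with a loess trend of fold change on transcript length and GC content removed.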

Results

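Gene expression was measured in the frontal cortex, the prelimbic and infralimbic area, of 32 mice that had received the gut microbiota of a primate donor. The donors were humans (12 mice), squirrel monkeys (8 mice) and macaques (12 mice). The study asks whether microbiota of larger-brained primates change gene expression in the mouse brain. The total count per mouse was 1204600 to 2089310 in the human group, 1193110 to 1588720 in the squirrel monkey group and 1035040 to 1673880 in the macaque group. All 32 mice carried counts of the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y. Every batch and every plate column held mice of 1 donor species, so each difference between donor groups below is also a difference between batches and plate columns.

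In mice given human rather than macaque microbiota, 19 of 40 ribosomal protein genes, some respiratory chain genes and 5 of 31 myelin genes were higher, and the channel genes Scn7a and Trpc5 were among those lower. Of 12651 genes, 565 were higher and 448 lower (edgeR quasi-likelihood test), with a median absolute log2 fold change of 0.37 among these genes. Syn1, which encodes the synaptic vesicle protein synapsin I, had the largest change by the naming rule (log2 fold change 5.79 ± 0.86 SE, adjusted p = 1.59e-05). Its mean was 177 ± 181 CPM (SD, n = 12) against 3.07 ± 1.35 CPM (SD, n = 12), and the human mice fell into separate levels. Rps16, a protein of the small ribosomal subunit, rose from 22.4 ± 5.74 to 60.6 ± 18.2 CPM (SD, n = 12 each; log2 fold change 1.42 ± 0.17 SE, adjusted p = 2.52e-07). Csrp1, a LIM-domain protein, rose from 18.6 ± 4.11 to 51.5 ± 19.7 CPM (log2 fold change 1.48 ± 0.19 SE, adjusted p = 8.80e-07).

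The other genes named as higher were Cd200r3 (log2 fold change 1.52), Adamts4, a protease (1.37), and the myelin gene Mog (1.43). The pseudogene Vmn1r-ps63 rose from 4.25 ± 2.25 to 12.1 ± 7.02 CPM, and the myelin gene Cldn11 from 42.6 ± 32.6 to 115 ± 140 CPM (SD, n = 12 each). The lower genes were led by Scn7a, a sodium channel (log2 fold change -1.35 ± 0.35 SE, adjusted p = 0.0111), whose mean was 6.46 ± 4.99 CPM against 16.8 ± 9.71 CPM (SD, n = 12 each). Next came Olfr1419 (-1.10), Efcab6 (-1.08), the chromatin remodelling subunit Smarcd3 (-0.86), Pcsk1n, the precursor proSAAS (-0.82), the clathrin adaptor subunit Ap2a1 (-0.80), Zkscan16 (-0.80) and the cation channel Trpc5 (-0.76). Without macaque replicate 12, Efcab6 no longer passed (-0.74). Ap2a1 was below the macaque median in 12 of 12 human mice, but it also differed between the human batches, as given further on. Several of these genes overlap another gene on the opposite strand and are uncertain for that reason: Syn1 (Timp1 and Araf), Smarcd3 (Chpf2), Pcsk1n (Eras), Ap2a1 (Fuz) and Trpc5 (Trpc5os). Adamts4, Mog and Efcab6 are uncertain for the same reason.

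Among the 40 ribosomal protein genes of the list, 19 rose, 0 fell and 21 did not pass (20 higher and 2 lower adjusted over the list alone). Rplp1 had a log2 fold change of 0.58, Rps20 1.06, Rpl19 1.10 and Rpl3 1.29. The list test gave adjusted p = 1.28e-14 (camera) and adjusted p = 0.311 with an estimated correlation. The score was 0.14 ± 0.06 in human mice and -0.17 ± 0.08 in macaque mice (SD, n = 12 each), a difference of 0.31 (permutation p = 1e-05, the smallest the resampling can give; adjusted p = 0.00014 over 28 tests), and 12 of 12 human mice lay above the macaque median. Near-identical copies of the 3′ end exist for 26 of the 40 genes, so values of single members such as Rpl19 are uncertain.

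Of 37 genes of respiratory complex I, 5 rose and 0 fell (5 and 0 adjusted over the list alone), led by Ndufb4 (log2 fold change 1.16), Ndufs5 (0.58), Ndufa7 (0.34) and Ndufa12 (0.50). Of 36 genes of complexes III to V, 6 rose and 0 fell (8 and 0 adjusted over the list alone), among them Atp5g1 (0.56), Cox6c (0.40), Atp5l (0.71) and Atp5g2 (0.78). The list tests gave adjusted p = 0.0114 and 0.0326 (camera), and adjusted p = 0.986 with an estimated correlation for both. The complex I score differed by 0.10 and did not pass (permutation p = 0.0651, adjusted p = 0.107 over 28 tests; 9 of 12 human mice above the macaque median). Neither list passed once a trend of fold change on transcript length and GC content was removed (adjusted p = 0.279 and 0.477, a check chosen after seeing the data): the mean excess over other genes went from 0.0800 (SD 0.237 over genes) to 0.0528 (SD 0.237) and from 0.0675 (SD 0.213) to 0.0416 (SD 0.222).

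Of 31 oligodendrocyte and myelin genes, 5 rose and 0 fell (26 and 0 adjusted over the list alone). Gjc3, a gap junction protein, had a log2 fold change of 0.81 and Mog of 1.43, and Mal rose from 68.2 ± 40.9 to 157 ± 167 CPM (SD, n = 12 each). The list test gave adjusted p = 6.31e-05 (camera) and adjusted p = 0.986 with an estimated correlation. Human mice varied widely in this group (score 0.18 ± 1.03, SD, n = 12, against -0.35 ± 0.53, SD, n = 12; permutation p = 0.124, adjusted p = 0.174 over 28 tests). Without the 5 mice of highest myelin score (human replicates 1, 4 and 12 and squirrel monkey replicates 1 and 8), an alternative chosen after seeing the data, the mean difference of the list was 0.0066 (SD 0.192 over genes, adjusted p = 0.989) in place of 0.535 (SD 0.234) and lay below that of other genes. Leaving out mice by this score lowers it by construction. Human mice of high myelin score had low upper cortical layer scores (r = -0.842, permutation p = 0.00132, adjusted p = 0.00396 over 6 sets; Spearman rho -0.678, permutation p = 0.0183, adjusted p = 0.0549; r = -0.544 without the 2 farthest mice). The calls of Cldn11, Mal and Mog were each lost without any 1 of human replicates 1, 4 and 12 or macaque replicates 1, 3, 4, 5, 7, 8, 9 and 12. Mal was also lost without human replicate 7 or macaque replicate 10, and Mog without human replicate 7, squirrel monkey replicates 2, 3, 4 or 6, or macaque replicates 2 or 11.

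Of 77 autism risk genes, 2 rose and 8 fell (3 and 10 adjusted over the list alone). Taok1 (log2 fold change -0.24), Ash1l (-0.23) and Ankrd11 (-0.22) fell. Of 59 schizophrenia risk genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone), among them Herc1 (-0.30), Rb1cc1 (-0.30), the transcription factor Mef2c (-0.33) and the GABA receptor subunit Gabbr2 (-0.40). The list tests gave adjusted p = 0.0154 for autism and 0.00651 for schizophrenia genes (camera), and adjusted p = 0.876 and adjusted p = 0.311 with an estimated correlation. The scores differed by -0.05 (permutation p = 0.0134, adjusted p = 0.0417 over 28 tests) and -0.08 (permutation p = 0.00239, adjusted p = 0.0134), with 2 of 12 human mice above the macaque median in each. Both lists were picked for this test after their list results were seen, so it is no separate support. With the trend on transcript length and GC content removed, neither list passed (adjusted p = 0.0717 for both), as the excess over other genes was smaller at a like spread: -0.0522 (SD 0.158) after and -0.0750 (SD 0.164) before for autism genes, and -0.0833 (SD 0.183) after and -0.108 (SD 0.187) before for schizophrenia genes.

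The count of 1013 fell to 337 without macaque batch F, 390 without batch E and 472 without human batch A. It was 506 with counts summed per batch (405 of them among the 1013) and 576 with library total as a covariate (521 among them). Scaling by library totals alone gave 673 higher and 321 lower genes in place of 565 and 448. With the ribosomal protein score as a covariate, an alternative chosen after seeing the data, 521 genes passed, only 158 of them among the 1013. The myelin, respiratory chain and autism lists changed direction relative to other genes. The autism list did not pass in the other direction (camera, adjusted p = 0.607), whereas the myelin and respiratory chain lists did. With the myelin score as a covariate, also chosen after seeing the data, the lists of complex I (mean difference 0.0866, SD 0.239, from 0.103, SD 0.228; adjusted p = 0.117), complexes III to V (0.0680, SD 0.207, from 0.0903, SD 0.198; adjusted p = 0.398) and autism genes (-0.0426, SD 0.159, from -0.0478, SD 0.157; adjusted p = 0.0855) no longer passed. Nor did they with batch as fixed levels (adjusted p = 0.163, 0.261 and 0.0509), where the mean differences were 0.0785 (SD 0.240), 0.0686 (SD 0.210) and -0.0397 (SD 0.162). Without the 5 mice both respiratory chain lists did not pass (0.0578 and 0.127), though their mean differences of 0.0951 (SD 0.246) and 0.0817 (SD 0.214) were about as large as before.

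**Figure D1:**
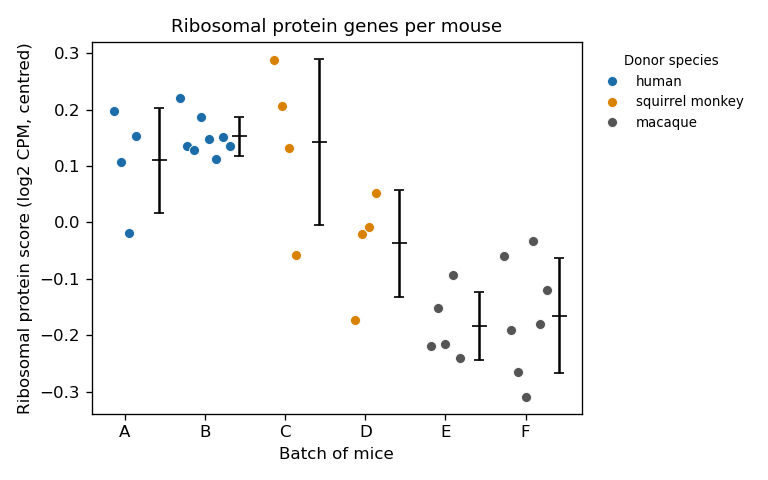
Ribosomal protein score of each mouse (mean centred log2 CPM of 40 genes, vertical axis) by batch A to F (horizontal axis), coloured by donor species; bars give mean ± SD of each batch. Macaque batches E and F average -0.18 and -0.17, human batches A and B 0.11 and 0.15, and squirrel monkey batches C and D 0.14 and -0.04.

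In mice given squirrel monkey rather than macaque microbiota, Syn1, Igf2 and 12 of 40 ribosomal protein genes were higher, and the channels Scn7a and Hcn4 were lower. Of 12651 genes, 49 were higher and 32 lower (edgeR quasi-likelihood test). Syn1 averaged 273 ± 111 CPM (SD, n = 8) against 3.07 ± 1.35 CPM (SD, n = 12), a log2 fold change of 6.41 ± 0.87 SE (adjusted p = 0.0001). An upper level held 7 of 8 squirrel monkey mice, and the remaining mouse was in the low level of the macaque mice. Igf2, a growth factor made in the meninges, rose from 3.28 ± 1.35 to 8.94 ± 3.60 CPM (log2 fold change 1.47 ± 0.31 SE, adjusted p = 0.0132), above the macaque median in 8 of 8 mice. Rps16 rose from 22.4 ± 5.74 to 48.0 ± 15.7 CPM (log2 fold change 1.07 ± 0.19 SE, adjusted p = 0.00315).

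The other genes named as higher were Nxph3, a neurexophilin (log2 fold change 1.21), the cytochrome c oxidase subunit Cox6a2 (1.15), Txnip, the thioredoxin-interacting protein (1.11), and the kinase anchor Akap12 (1.03). The semaphorin Sema5b rose from 14.5 ± 5.53 (SD, n = 12) to 28.6 ± 9.46 CPM (SD, n = 8). The lower genes were Scn7a (-1.82), Hcn4, a pacemaker channel (-1.40), Olfr1419 (-1.24), Ace, the angiotensin-converting enzyme (-1.03), Ppp2r1b (-0.96), the sorting receptor Sorcs1 (-0.77), Mgat5b (-0.74) and Sccpdh (-0.68). Igf2 (Igf2os), Cox6a2 (Itgad), Ppp2r1b (Sik2) and Txnip (Gm15441) overlap genes on the opposite strand, and Igf2 has 1 near-identical copy of its 3′ end, so these values are uncertain. Sema5b, Ace and Sorcs1 also overlap genes on the opposite strand and are likewise uncertain. Without squirrel monkey replicate 2, neither Igf2 (1.37) nor Ppp2r1b (-0.90) passed. Ace was lost without squirrel monkey replicates 4 or 7 (-0.95 to -1.12 over all removals of 1 mouse). Akap12 was lost without squirrel monkey replicates 1, 2, 3, 6, 7 or 8 or macaque replicates 1, 3, 5, 8 or 9 (0.86 to 1.18 over all removals of 1 mouse). Nxph3 was lost without squirrel monkey replicates 1, 2, 3, 4, 7 or 8 or macaque replicates 1, 3, 5, 7, 8, 9 or 12 (1.10 to 1.35 over all removals of 1 mouse). Sccpdh was lost without squirrel monkey replicates 1, 2, 4 or 7 (-0.62 to -0.79 over all removals of 1 mouse). Scn7a was lost without squirrel monkey replicates 1, 2, 3, 4, 7 or 8 or macaque replicates 3, 5, 7, 8, 9 or 12 (-1.64 to -2.14 over all removals of 1 mouse). Sorcs1 was lost without squirrel monkey replicates 1, 2, 3, 4 or 7 or macaque replicates 3, 8, 9 or 12 (-0.69 to -0.82 over all removals of 1 mouse). Txnip was lost without squirrel monkey replicates 1, 2, 7 or 8 or macaque replicate 8 (0.99 at the lowest over all removals of 1 mouse).

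Of the 40 ribosomal protein genes, 12 rose and 0 fell (17 and 0 adjusted over the list alone), with log2 fold changes of 0.37 for Rpl37, 0.90 for Rpl3, 0.89 for Rps6 and 0.34 for Rps9. The list test gave adjusted p = 2.60e-14 (camera) and adjusted p = 0.355 with an estimated correlation. The score was 0.05 ± 0.15 (SD, n = 8), a difference of 0.23 from macaque mice (exact permutation p = 0.000318, adjusted p = 0.00296 over 28 tests), with 8 of 8 mice above the macaque median. Complex I had 1 gene that rose, Ndufb4 (log2 fold change 0.84), and 0 that fell among 37 (2 and 0 adjusted over the list alone). Complexes III to V had 0 of 36 (3 and 0 adjusted over the list alone). Their list tests gave adjusted p = 0.0219 and 0.00956 (camera), and adjusted p = 0.82 with an estimated correlation for both; with the trend on transcript length and GC content removed, adjusted p was 0.874 and 0.746, and the excess over other genes 0.0143 (SD 0.159) and 0.0158 (SD 0.133) in place of 0.0605 (SD 0.161) and 0.0616 (SD 0.119). The complex I score differed by 0.08 and did not pass (exact permutation p = 0.192, adjusted p = 0.245; 6 of 8 mice above the macaque median). Ndufb4 was lost without squirrel monkey replicate 1 or 2.

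Members of 4 further lists were higher on balance without passing singly, except Igf2. In the oligodendrocyte and myelin list 0 of 31 genes passed (0 adjusted over the list alone) with all 31 fold changes positive, and the list test gave adjusted p = 5.51e-08 (camera) and adjusted p = 0.654 with an estimated correlation. The myelin score differed by 0.62 and did not pass (exact permutation p = 0.0432, adjusted p = 0.0962 over 28 tests; 7 of 8 mice above the macaque median). Without the 5 mice of highest myelin score, 2 of them in this group, the list's mean difference was 0.258 (SD 0.200) in place of 0.615 (SD 0.261) and still passed (adjusted p = 0.00321). In the glucocorticoid response list 0 of 21 passed (6 higher adjusted over the list alone), with log2 fold changes of 0.59 for Mt2, 0.45 for Fkbp5 and 0.47 for Tsc22d3; the list test gave adjusted p = 3.67e-05 and adjusted p = 0.522 with an estimated correlation. The glucocorticoid score differed by 0.29 and did not pass (exact permutation p = 0.0222, adjusted p = 0.0565; 7 of 8 mice above the macaque median). In the meninges and fibroblast list 1 of 15 genes rose, Igf2 (1 adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.522 with an estimated correlation). In the blood cell list 0 of 6 passed (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.522 with an estimated correlation), with log2 fold changes of 1.10 for Hba-a2 and 0.63 for Hbb-bs.

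Lower on balance were 4 lists. Of 17 upper cortical layer genes 0 passed (1 higher and 5 lower adjusted over the list alone), with -0.78 for Cux2 and -0.74 for Lmo4, while Lamp5 had 0.45. The upper layer score differed by -0.20 (exact permutation p = 0.00892, adjusted p = 0.0357 over 28 tests) and 0 of 8 mice lay above the macaque median. It ran against the myelin score (r = -0.691 over 32 mice with group means removed, permutation p = 3e-05, adjusted p = 0.00018 over 6 sets; Spearman rho -0.597, permutation p = 0.00041, adjusted p = 0.00246; r = -0.55 without the 2 farthest mice). It was r = -0.624 in the 8 squirrel monkey mice (exact permutation p = 0.105) and -0.0675 there without the 2 farthest. The upper layer list had a mean difference of -0.112 (SD 0.288) in place of -0.195 (SD 0.398) and did not pass with the myelin score as a covariate (adjusted p = 0.167). Nor did it without the 5 mice of highest myelin score (-0.142, SD 0.328; adjusted p = 0.0948) or with batch as fixed levels (-0.192, SD 0.399; adjusted p = 0.0515). Of 21 deep cortical layer genes 0 passed (1 higher and 1 lower adjusted over the list alone), and 16 had positive fold changes (mean log2 fold change 0.13). The deep layer list did not pass (adjusted p = 0.101, camera; adjusted p = 0.755 with an estimated correlation). Of 28 postsynaptic scaffold genes 0 passed (1 lower adjusted over the list alone; Lrrtm1 -0.44). Of 59 schizophrenia risk genes 1 fell, the calcium channel Cacna1g (-0.45; 2 lower adjusted over the list alone), and of 77 autism risk genes 0 passed (0 adjusted over the list alone). The list tests gave adjusted p = 0.0359, 0.0188, 0.049 and 0.00801 in this order (camera), and adjusted p = 0.522 for upper layer, schizophrenia and autism genes and adjusted p = 0.534 for scaffold genes with an estimated correlation. The autism score differed by -0.06 (exact permutation p = 0.0108, adjusted p = 0.0378 over 28 tests) and the schizophrenia score by -0.06 (exact permutation p = 0.0168, adjusted p = 0.0471), with 2 of 8 mice above the macaque median in each. As the scored lists were picked after the list results were seen, these score tests, and that of upper layer genes, are no separate support. With the trend on transcript length and GC content removed, none of these 4 lists passed (adjusted p = 0.0667, 0.168, 0.402 and 0.402 in the same order), nor did the blood cell list (0.0577). The excess over other genes was then -0.195 (SD 0.405) from -0.223 (SD 0.406) for upper layer genes, -0.0733 (SD 0.174) from -0.109 (SD 0.175) for scaffold genes, -0.0557 (SD 0.222) from -0.0867 (SD 0.221) for schizophrenia genes, -0.0343 (SD 0.131) from -0.0738 (SD 0.137) for autism genes and 0.452 (SD 0.484) from 0.510 (SD 0.492) for blood cell genes. Cacna1g was lost without human replicates 1, 4, 5, 6, 9 or 11, squirrel monkey replicates 1, 2, 3, 7 or 8, or macaque replicates 1, 3, 4, 8, 9 or 12 (-0.39 to -0.50 over all removals of 1 mouse). Where 0 members passed in edgeR, 1667 of all 12651 genes had an unadjusted p under 0.05.

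The count fell from 81 to 0 without macaque batch F (edgeR; 1403 genes at an unadjusted p under 0.05), to 10 without batch E and to 2 without squirrel monkey batch C. It was 28, 32 and 51 without squirrel monkey replicates 2, 1 and 8, and 131 and 122 without macaque replicates 6 and 10; with the ribosomal protein score as a covariate it was 17, of which 1 was among the 81. With counts summed per batch it was 203, of which 54 were among the 81, whereas batch as a random effect lowered it, as given further on. With the myelin score as a covariate, the lists of complex I (mean difference 0.0560, SD 0.162, from 0.0753, SD 0.154; adjusted p = 0.167), complexes III to V (0.0510, SD 0.124, from 0.0767, SD 0.113; 0.167) and postsynaptic scaffold (-0.0468, SD 0.138, from -0.0924, SD 0.160; 0.404) did not pass. Neither did those of meninges (0.228, SD 0.286, from 0.406, SD 0.335; 0.0506), blood cell (0.321, SD 0.344, from 0.400, SD 0.387; 0.169) and schizophrenia genes (-0.0573, SD 0.172, from -0.0647, SD 0.212; 0.106). All of these but meninges also did not pass without the 5 mice (adjusted p = 0.201, 0.0948, 0.141, 0.059 and 0.0833). The mean differences were then 0.0517 (SD 0.142), 0.0563 (SD 0.109), -0.0666 (SD 0.133), 0.361 (SD 0.341) and -0.0618 (SD 0.187) in the same order, the last 2 about as large as before. The blood cell and schizophrenia lists also missed the threshold with batch as fixed levels (0.0515 for both; mean differences 0.397, SD 0.381, and -0.0626, SD 0.212). They missed it without ribosomal protein genes (0.0511 and 0.0554), where the mean differences were those reported, and with library total as a covariate (0.0517 and 0.0508; 0.397, SD 0.385, and -0.0646, SD 0.212).

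**Figure D2:**
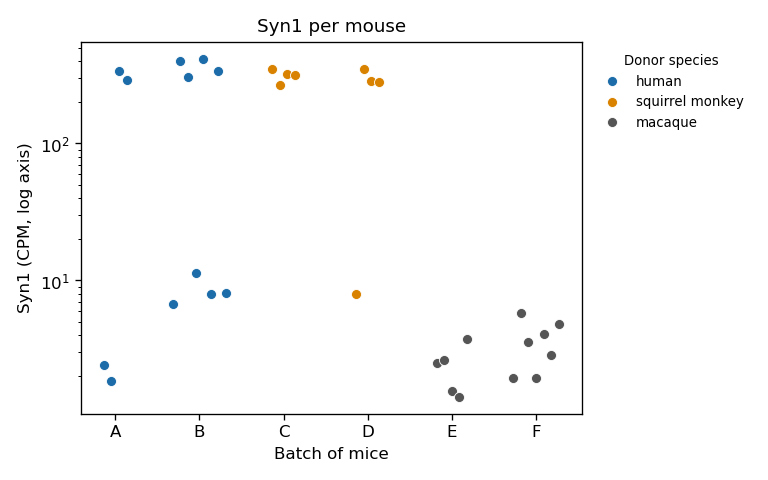
Syn1 in each mouse (CPM, log axis, vertical) by batch A to F (horizontal), coloured by donor species. The 13 mice of the upper level lie between 269 and 415 CPM and the 19 of the lower level between 1.42 and 11.4 CPM; all 12 macaque mice are in the lower level.

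Between the human and squirrel monkey groups few genes differed, and by small amounts. Of 12651 genes, 2 were higher and 15 lower in mice given human microbiota (edgeR quasi-likelihood test), and 1267 had an unadjusted p under 0.05. None of these 17 passed with counts summed per batch or without squirrel monkey batch D. Spc24 then had a log2 fold change of -0.59 and -0.42. By contrast, DESeq2, limma voom with sample weights, batch as fixed levels and fits without batch B or C gave more genes than 17, as given further on. Spc24, a kinetochore protein, was lowest in p (71.5 ± 9.82 CPM, SD, n = 12, against 105 ± 16.2 CPM, SD, n = 8; log2 fold change -0.56 ± 0.08 SE, adjusted p = 0.000678), and 0 of 12 human mice lay above the squirrel monkey median. The higher genes were the zinc finger gene Zfp771 (0.52) and Ei24 (0.29). Also lower were Eef1akmt3 (-0.47), Zfp316 (-0.42), the inositol phosphate kinase Ip6k2 (-0.40), the synaptic scaffold gene Dlgap2 (-0.36), Scaper (-0.36) and the Golgi protein Golgb1 (-0.35). None of the 43 lists passed (camera, with a preset or an estimated correlation), and 0 lists had an unadjusted p under 0.05 with an estimated correlation. None of the 7 list scores tested passed (adjusted p = 0.137 to 0.848, from exact permutation over 28 tests). Eef1akmt3 (Mettl1), Golgb1 (4930565N06Rik), Ei24, Ip6k2 and Dlgap2 overlap genes on the opposite strand and are uncertain. The calls of 9 of the 10 genes taken by the naming rule, all but Spc24, were lost without any 1 of 8 to 27 mice, and the count of 17 became 2 without human replicate 2, 9 or 10 or squirrel monkey replicate 5, 6 or 7, 3 without squirrel monkey replicate 8, 6 without squirrel monkey replicate 2 or 4, and 7, 8 and 11 without human replicates 1 and 3 and squirrel monkey replicate 3. It became 29, 67 and 30 without human replicates 11 and 12 and squirrel monkey replicate 1.

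The mean of the human and squirrel monkey groups was compared with the macaque group. This contrast follows the study's own grouping of donors as larger-brained. Brain size of the donors was not part of the data used here. Higher were Syn1, 18 of 40 ribosomal protein genes, 5 of 37 genes of complex I and 4 of 36 of complexes III to V, and lower were Scn7a, Olfr1419 and Hcn4. Of 12651 genes, 342 were higher and 355 lower (edgeR quasi-likelihood test); scaling by library totals alone gave 408 and 231. Syn1 had a log2 fold change of 6.10 ± 0.82 SE (adjusted p = 5.20e-06), but only 6 of 12 human and 7 of 8 squirrel monkey mice were in its upper level. The others shared the low level of all macaque mice, although 18 of 20 mice lay above the macaque median. Csrp1 (1.24 ± 0.18 SE, adjusted p = 1.65e-05) and Rps16 (1.24 ± 0.16 SE, adjusted p = 2.00e-06) lay above it in 20 of 20 mice. Nxph3 (1.26), Igf2 (1.23), the sulfatase Arsg (1.20), Tmem63a (1.20) and Vmn1r-ps63 (1.19) were also higher. Lower were Scn7a (-1.59 ± 0.32 SE, adjusted p = 0.00195), Olfr1419 (-1.17), Clec18a (-1.15), Efcab6 (-1.04), the matrix protein Smoc2 (-0.94), Hcn4 (-0.94), the polysialyltransferase St8sia2 (-0.89) and the sulfatase Arsj (-0.89). Arsg overlaps Slc16a6 on the opposite strand and is uncertain. Tmem63a, Efcab6, Smoc2, St8sia2 and Arsj also overlap genes on the opposite strand and are likewise uncertain. Efcab6 no longer passed without macaque replicate 12 (-0.70). Tmem63a was lost without human replicate 4, squirrel monkey replicates 1, 2 or 8, or macaque replicates 1, 3, 4, 5, 7, 8, 9, 11 or 12 (1.04 to 1.37 over all removals of 1 mouse). St8sia2 was lost without human replicates 4 or 7, squirrel monkey replicates 1, 2, 3, 7 or 8, or macaque replicates 1, 5, 7, 9, 11 or 12 (-0.76 to -0.99 over all removals of 1 mouse). Arsj was lost without human replicates 1, 2, 4, 5, 7, 9 or 12, squirrel monkey replicates 1, 2, 4, 7 or 8, or macaque replicates 1, 2, 3, 5, 8, 9 or 12 (-0.76 to -0.98 over all removals of 1 mouse).

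In this comparison 18 of 40 ribosomal protein genes rose and 0 fell (21 and 0 adjusted over the list alone), among them Rps20 (log2 fold change 0.85), Rpl3 (1.10), Rps6 (1.07) and Rplp1 (0.44). The list test gave adjusted p = 7.26e-17 (camera) and adjusted p = 0.195 with an estimated correlation. Score tests of this comparison pooled the 20 mice, and the ribosomal score differed by 0.28 (permutation p = 1e-05, adjusted p = 0.00014 over 28 tests; 20 of 20 mice above the macaque median). With the groups weighted equally its difference was 0.27. Complex I had 5 of 37 higher and 0 lower (5 and 0 adjusted over the list alone; Ndufs5 0.45), and complexes III to V had 4 of 36 higher and 0 lower (7 and 0 adjusted over the list alone; Atp5l 0.60). Their tests gave adjusted p = 0.00494 and 0.00537 (camera), and adjusted p = 0.801 with an estimated correlation for both; with the trend on transcript length and GC content removed, adjusted p was 0.368 and 0.477, and the excess over other genes 0.0335 (SD 0.194) and 0.0287 (SD 0.174) in place of 0.0702 (SD 0.195) and 0.0646 (SD 0.162). Of 31 oligodendrocyte and myelin genes 1 rose, Gjc3 (0.67; 24 higher adjusted over the list alone; adjusted p = 1.58e-07, and adjusted p = 0.756 with an estimated correlation). Of 21 glucocorticoid response genes 1 rose, Ddit4 (0.67; 5 higher adjusted over the list alone), and of 15 meninges and fibroblast genes 1 rose, Igf2 (1 adjusted over the list alone); both tests gave adjusted p = 0.00494 (camera) and adjusted p = 0.756 with an estimated correlation. The scores of complex I (difference 0.09, permutation p = 0.0481, adjusted p = 0.0962 over 28 tests; 15 of 20 mice above the macaque median), myelin (0.57, permutation p = 0.0568, adjusted p = 0.0998; 16 of 20) and glucocorticoid genes (0.18, permutation p = 0.057, adjusted p = 0.0998; 16 of 20) did not pass, nor did that of upper layer genes (-0.12, permutation p = 0.0477, adjusted p = 0.0962; 5 of 20). Gjc3 was lost without human replicates 1, 2, 3, 4 or 7, squirrel monkey replicates 1, 2, 3, 4 or 8, or macaque replicates 1, 2, 3, 4, 5, 7, 8, 9, 11 or 12 (0.59 to 0.82 over all removals of 1 mouse). Ddit4 was lost without squirrel monkey replicates 2 or 3 or macaque replicates 1, 3, 4, 5 or 8 (0.56 to 0.73 over all removals of 1 mouse).

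Of 77 autism risk genes 1 rose and 6 fell, the latter including Taok1 (-0.21), Ash1l (-0.18) and Ankrd11 (-0.16) (1 and 10 adjusted over the list alone). Of 59 schizophrenia risk genes 0 rose and 5 fell, among them Mef2c (-0.29), Gabbr2 (-0.37), Sorcs3 (-0.63) and Rb1cc1 (-0.19) (0 and 9 adjusted over the list alone). Both list tests gave adjusted p = 0.00494 (camera), and adjusted p = 0.548 for autism and adjusted p = 0.407 for schizophrenia genes with an estimated correlation. The scores differed by -0.05 (permutation p = 0.00342, adjusted p = 0.016 over 28 tests) and -0.07 (permutation p = 0.00058, adjusted p = 0.00406), with 4 of 20 mice above the macaque median in each. Here too the score tests of both lists are no separate support. With the trend on transcript length and GC content removed, neither passed (adjusted p = 0.135 and 0.122), as the excess over other genes was smaller at a like spread: -0.0433 (SD 0.134) after and -0.0744 (SD 0.139) before for autism genes, and -0.0695 (SD 0.191) after and -0.0973 (SD 0.192) before for schizophrenia genes. Ankrd11 was lost without squirrel monkey replicates 1 or 2 or macaque replicates 9 or 12 (-0.15 to -0.18 over all removals of 1 mouse).

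The count of 697 fell to 73 without macaque batch F, 172 without batch E and 206 without squirrel monkey batch C. With the ribosomal protein score as a covariate it was 274, of which 42 were among the 697, and 6 of the 8 lists past the threshold changed direction relative to other genes. Complex I, complexes III to V and myelin then passed as lower (camera, adjusted p = 2.07e-06, 3.71e-07 and 0.0477). Glucocorticoid, meninges and autism genes did not pass in either direction (adjusted p = 0.932, 0.577 and 0.811). With the myelin score as a covariate the lists of complex I (mean difference 0.0713, SD 0.197, from 0.0894, SD 0.187; adjusted p = 0.0992), complexes III to V (0.0595, SD 0.161, from 0.0835, SD 0.151; 0.156) did not pass. Neither did those of glucocorticoid (0.0944, SD 0.136, from 0.201, SD 0.160; 0.327) and meninges genes (0.187, SD 0.226, from 0.354, SD 0.286; 0.156). These 4 lists also did not pass without the 5 mice of highest myelin score (adjusted p = 0.0616, 0.0616, 0.061 and 0.0702). Their mean differences were then 0.0734 (SD 0.190), 0.0690 (SD 0.155), 0.153 (SD 0.150) and 0.233 (SD 0.237). The myelin list then had 0.132 (SD 0.177) in place of 0.575 (SD 0.240; adjusted p = 0.227).

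**Figure D3:**
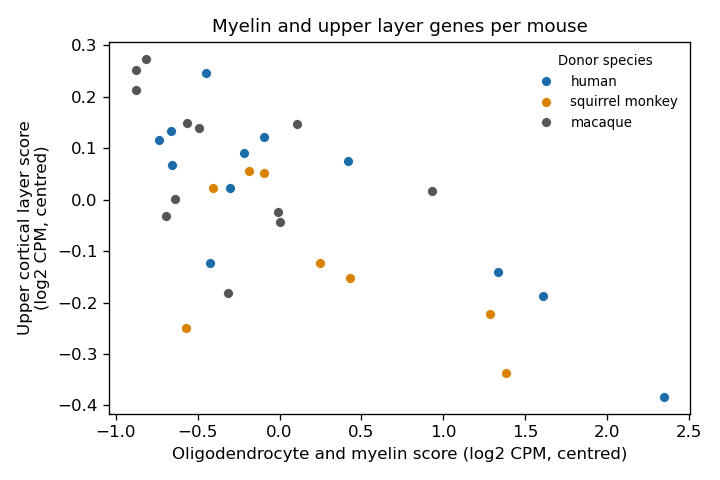
Upper cortical layer score (vertical axis) against oligodendrocyte and myelin score (horizontal axis) of each mouse, both in centred log2 CPM, coloured by donor species; each point is 1 mouse. Mice of high myelin score have low upper layer scores; with donor group means removed, r was -0.691 over 32 mice.

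Over all 3 donor groups, 778 genes differed in the F-test. The count was 231, 268 and 379 without batches F, E and A, 420 with counts summed per batch, 426 with library total as a covariate and 319 with the ribosomal protein score as a covariate. Between batches of the same donor species, 3 genes were higher in human batch B than in batch A (Fscn1, an actin-bundling protein, log2 fold change 0.48; Eif5a, 0.47; Ap2a1, 0.89) and 0 lower, with 1473 genes at an unadjusted p under 0.05. Slc7a11 (-0.68), Phkg1 (-0.66) and Trim56 (-0.82) had the smallest p among those lower in batch B and did not pass. The batches held 4 (A), 8 (B), 4 (C), 4 (D), 5 (E) and 7 (F) mice. Batch comparisons thus rest on fewer mice than those between donor groups, and their counts of genes are not directly comparable. At an unadjusted p under 0.05 (edgeR), human against squirrel monkey had 1267 genes and squirrel monkey against macaque 1667. Between squirrel monkey batches D and C 0 genes passed in edgeR (883 at an unadjusted p under 0.05). The smallest p there belonged to Olfr1116 (0.87), Ncf1 (1.05) and Thpo (1.08) in one direction and to the ribosomal protein genes Rpl7 (-0.63), Rpl7a (-0.81) and Rpl19 (-0.71) in the other. Between macaque batches F and E 0 genes passed in edgeR (399 at an unadjusted p under 0.05); Utrn (0.47), Cast (0.51), Ankrd45 (-0.53), Ttc5 (-0.49) and Ankrd37 (-1.02) were among those of smallest p. At the preset correlation, 11, 7 and 6 lists passed in these 3 batch comparisons, as many as between donor groups (6, 11, 0 and 8); with an estimated correlation 0 lists passed in every comparison (camera). At an unadjusted p under 0.05 and an estimated correlation there were 2 lists in human against macaque, 3 in squirrel monkey against macaque and 3 in the combined comparison.

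Fold changes against the macaque group were correlated across genes between the human and squirrel monkey comparisons (r = 0.72, covariance 0.0409), across 12651 genes that are not independent replicates. Both share the macaque mice, and 20 simulations of unchanged groups gave r = 0.456 and covariance 0.0107. With macaque batch E for one comparison and batch F for the other, r was 0.489 and 0.476, and covariance 0.0341 in both. Genes higher in both comparisons numbered 41 and genes lower in both 20. In the same simulations 0 genes on average passed in both (likelihood ratio test), and lists of as many top genes per direction shared 19.6 higher (at most 25) and 9.65 lower genes (at most 14). Independent lists would share 2.19 and 1.13, a value that leaves out the shared macaque mice. With batch E for human and F for squirrel monkey 17 genes were higher and 1 lower in both, and with F and E 6 and 0.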

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

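The splits of mice into other groups were planned before their results were seen; every test of a pattern in this part was chosen after the result was seen.

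In the squirrel monkey group, 4 of 108 results had a mouse far from the other 7; chance alone gives about 1 in 20. Replicate 5 had 7.98 CPM of Syn1, where the others had 269 to 351 CPM. Replicate 6 had 12.8 CPM of Scn7a (others 0.661 to 5.99), 115 CPM of Sccpdh (others 57.0 to 81.2) and 1491 CPM of Mef2c (others 1115 to 1279). The human and macaque groups exceed 10 mice and were not tested in this way.

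The higher ribosomal protein genes of the human and squirrel monkey groups were weighed against technical causes. Members without a near-identical copy of their 3′ end still differed by 0.306 log2 CPM (14 genes, permutation p = 2e-05), so reads shared with copies do not account for all of it; Spearman rho of fold change and copy number was -0.0765 across the 40 genes and 0.146 across all 94 Rpl and Rps genes, so a part of shared reads stays open. After a trend on transcript length and GC content was removed, the excess over other genes was 0.225 (SD 0.352) and still past the threshold, from 0.263 (SD 0.348) before. Batch, plate column or library preparation cannot be told apart from donor species: squirrel monkey batch D differed from C by -0.18 against 0.269 between donor groups (absolute value 0.18 in the test), and no batch or column mixes donors. A biological effect of the microbiota stays open and untested against these.

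Oligodendrocyte and myelin genes varied most among mice within groups. Mice with high myelin scores had low upper layer scores (r = -0.691, permutation p = 3e-05, bootstrap interval -0.862 to -0.418; Spearman rho -0.597, permutation p = 0.00041; adjusted p = 0.00018 and 0.00246 over 6 sets; r = -0.55 without the 2 farthest mice), which is what differing amounts of white matter in the dissections could give. Within groups r was -0.842 (human, permutation p = 0.00132), -0.624 (squirrel monkey, exact permutation p = 0.105) and -0.429 (macaque, permutation p = 0.167), and within batches -0.813 (B, exact permutation p = 0.0401) and -0.403 (F, exact permutation p = 0.347); in squirrel monkey mice it rested on 2 mice (-0.0675 without them). The difference of group medians was 0.438 against 0.575 for means in the combined comparison, 0.270 against 0.535 for human and 0.605 against 0.615 for squirrel monkey against macaque, so medians and means lay closer in the latter and whether a few mice carry the human difference stays open. A change in oligodendrocytes with donor species stays open and was not tested apart from dissection.

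Syn1 had 2 separate levels, with a gap of 4.41 log2 units and 0 mice between them. Among gaps with at least 3 mice on each side, no other gene had a gap over 2 (the next was 1.05). The upper level held 6 of 12 human, 7 of 8 squirrel monkey and 0 of 12 macaque mice (Fisher's exact p = 0.000446, two-sided, human and squirrel monkey against macaque). Both levels occurred within 3 batches, and within 1 batch for 2 donor species, which argues against batch alone and against donor species alone as the cause. An X-linked sequence variant that removes the counted 3′ end may give such levels, as all 32 mice carry Y-linked counts, but the counts hold no alleles and cannot decide it. Overlapping genes on the other strand also stay open.

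Among 100 splits of the mice into groups of the same sizes, the real one included, the real split gave the most genes in all 5 tests. A share of 1 in 100 is the smallest that so many splits can give, and the 5 tests share mice. The splits moved single mice across batches, so they cannot separate donor species from batch. In human against macaque it gave 1013 genes (highest other 242), in squirrel monkey against macaque 81 (highest other 3), in human against squirrel monkey 17 (highest other 4), in the combined comparison 697 (highest other 43), and in the F-test 778 (highest other 156); in each, 1 of 100 splits gave as many. Numbers of gene lists did not exceed chance: 66 of 100 splits gave at least 6 lists in human against macaque (highest other 25), 25 gave at least 11 in squirrel monkey against macaque (highest other 20), 51 gave at least 8 in the combined comparison (highest other 22), and all 100 gave at least 0 in human against squirrel monkey (highest other 23). Between human batches, 8 of 100 splits gave at least 3 genes; another split gave 365, which points to a structure among these mice that was not examined. Between squirrel monkey batches all 35 splits gave 0 genes (highest other 0), and between macaque batches all 100 gave at least the real 0 (highest other 4).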

How the results depend on the processing

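Ranked list tests, fits with covariates from gene scores, fits without ribosomal protein genes and without the 5 mice of highest myelin score were chosen after seeing the data, as was the library total covariate for lists; the other alternatives were planned. The number of genes stayed within 1.5 times the reported one in 17 of 24 alternatives for human against macaque (774 to 1313), 14 of 23 for the combined comparison (505 to 1024), 16 of 23 for the F-test (527 to 1097), 9 of 24 for squirrel monkey against macaque (76 to 93) and 7 of 24 for human against squirrel monkey (15 to 22). Unless a cause is named, the cause was not tested.

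Of 108 called values of named genes, the ribosomal protein score as a covariate kept 21, the fewest of the alternatives run (46 without batch F), ended 79 and reversed 8, while gene counts were lower without batch F in the comparisons with macaque and in the F-test. It left 521 genes in human against macaque (158 shared with the 1013 reported), 17 in squirrel monkey against macaque (1 shared), 80 in human against squirrel monkey, 274 in the combined comparison (42 shared) and 319 in the F-test. The reversed values were Cldn11 (-0.25), Mog (-0.036), Mal (-0.20) and Scn7a (0.48) in human against macaque, and Clec18a (0.24), Smoc2 (0.14), Arsj (0.048) and Atp5o (-0.046) in the combined comparison. Lists past the threshold became 10, 13, 11 and 10 in the 4 comparisons. Directions relative to other genes reversed, with mean differences in human against macaque of -0.165 (complex I), -0.187 (complexes III to V), -0.536 (myelin) and 0.0264 (autism). In squirrel monkey against macaque they were -0.119 (complex I), -0.125 (complexes III to V), 0.00106 (postsynaptic scaffold), -0.161 (myelin), 0.00122 (meninges), -0.00373 (autism) and 0.00163 (schizophrenia). In the combined comparison they were -0.142 (complex I), -0.156 (complexes III to V), 0.00804 (glucocorticoid), -0.348 (myelin), -0.128 (meninges) and 0.0113 (autism). Of these lists, both respiratory chain lists passed in the other direction in each of these comparisons. Myelin did so in human against macaque and in the combined comparison. The rest did not pass in either direction. The score itself differs between donor groups, so this fit also removes part of any group effect, and for the ribosomal list it gives no value by construction. No other alternative reversed a named gene.

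In human against macaque the count was 506 with counts summed per batch, 576 with library total as a covariate, 390 at a threshold of 0.01, and 472, 390 and 337 without batches A, E and F. In squirrel monkey against macaque it was 154 (DESeq2), 292 (limma voom with sample weights), 44 (batch as a random effect), 203 (summed per batch), 178 (only the groups compared), 19 (threshold 0.01), and 151, 2, 10 and 0 without batches B, C, E and F (edgeR, with 1403 genes at an unadjusted p under 0.05 without F). It was 48 without ribosomal protein genes, 40 with the myelin score, 22 without the 5 mice and 206 with the receptor score. In human against squirrel monkey it was 1 without a filter, 89 (DESeq2), 80 (voom), 46 (batch as fixed levels), 1 (summed per batch, 0 of the 17 kept), 3 (only the groups compared), 1 (library total), 2 (threshold 0.01), 3, 58, 63, 1 and 2 without batches A to E (0 of the 17 kept without D), 29 (myelin score), 39 (without the 5 mice) and 78 (receptor score). In the combined comparison it was 221 (threshold 0.01), 445, 206, 172 and 73 without batches A, C, E and F, 367 (myelin score), 376 (without the 5 mice) and 1047 (receptor score). In the F-test it was 420 (summed per batch), 426 (library total), 288 (threshold 0.01), and 379, 268 and 231 without batches A, E and F. Leaving out a batch also leaves fewer mice, and how much of the loss follows from that was not tested. Batch B against A gave 6 without a filter and 0 with only these batches (edgeR, 1339 at an unadjusted p under 0.05), and batch D against C gave 3 with only these batches.

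With each mouse left out in turn, counts ranged from 770 to 1146 (human against macaque), 28 to 131 (squirrel monkey against macaque), 2 to 67 (human against squirrel monkey), 475 to 803 (combined), 560 to 877 (F-test), 0 to 5 (batch B against A), 0 to 0 (D against C) and 0 to 0 (F against E). Of the 108 called values of named genes, 32 were lost without some mouse: 4 of 38 in human against macaque, 11 of 22 in squirrel monkey against macaque, 9 of 10 in human against squirrel monkey and 8 of 38 in the combined comparison. Without the 5 mice of highest myelin score 38 were lost, and with the myelin score as a covariate 27. Without batches E and C 49 and 42 were lost. Counts summed per batch ended 24 and batch as a random effect 21, while DESeq2 ended 7 and the receptor score 0.

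With an estimated correlation 0 lists passed in the comparisons with macaque (camera; 2, 3 and 3 at an unadjusted p under 0.05). The myelin score as a covariate gave 2, 4 and 3 lists in these comparisons, and not all of the 4 were among those reported. Leaving out the 5 mice gave 3, 5, 4 and 3 lists in the order human against macaque, squirrel monkey against macaque, human against squirrel monkey and combined. The myelin list then had a mean difference of 0.0066 in human against macaque, reversed relative to other genes, which follows from choosing mice by that score. Library total as a covariate gave 12 lists in human against macaque and 3 in human against squirrel monkey. Batch as fixed levels gave 2 in human against squirrel monkey, and the receptor score 13 in the combined comparison. Camera on ranked edgeR statistics gave 1 list in human against squirrel monkey and kept every list reported in the others. With the trend on transcript length and GC content also removed, 2, 6, 2 and 5 lists passed, of which 2, 4, 0 and 4 were among those reported. The trend removal also lowered the excess over other genes of the lists it ended, at a like spread; the mean over members itself stayed about as large in human against macaque for autism (-0.0553, from -0.0470) and schizophrenia genes (-0.0863, from -0.0798). The correlation of fold changes was 0.489 and 0.476 with the macaque batches split. The sex-linked covariate was not run, because Xist was not measured here and all mice carry Y-linked counts. No paired analysis was possible because each mouse and each batch belongs to a single donor species, so the design holds no pairs. The labels carry no replicate numbers. Those used here were assigned within each donor group in the order of the samples. At 1035040 to 2089310 counts per mouse, 20.9% of the smallest simulated changes were recovered in human against macaque, so small changes may be missed; the threshold of 0.01 leaves 390 genes there.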

Other observations

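The relations of the ribosomal protein score given here were chosen after the result was seen.

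Genes of olfactory and vomeronasal receptors took 0.697% to 1.68% of counts per mouse. Of 371 such genes tested, 26 were higher and 5 lower in human against macaque mice and 0 and 1 in squirrel monkey against macaque. Genes whose transcripts match mitochondrial protein-coding genes numbered 16 and took 4.25% to 6.47% of counts, of which 14 were tested, 1 higher and 5 lower in human against macaque mice. The counts hold 0 rows for genes encoded in the mitochondrial genome, so those genes were not analysed here. Whether the matching rows hold reads of the mitochondrial genes themselves was not tested. Gm29216, a match of mt-Co1 at 99.8% identity, had the highest mean of all genes (10442 CPM). Gm13341 (95.9% identity, mean 140 CPM) and Gm28661 (100% identity, mean 5225 CPM) both match mt-Co2 and were chosen after their values were seen. Gm13341 was higher in human against macaque mice (log2 fold change 1.33 ± 0.17 SE, adjusted p = 1.27e-06), while Gm28661 had -0.09 ± 0.06 SE (adjusted p = 0.365).

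The main axis of variation among mice was not donor species. The first principal component held 28.3% of the variance of the 500 most variable genes, with myelin genes such as Mbp and Mag at one end and Lmo4 and Synpr at the other, and donor group held 25.2% of it. The end of Lmo4 also held Scn7a, Clec18a, Smoc2 and St8sia2, which were named as lower against macaque mice. The myelin end also held Syn1, Cldn11 and Mog, which were named as higher. The second held 13.3%, of which donor group held 42.2% and batch 49.3%. Median correlations of log2 CPM between mice were 0.962 within a batch, 0.962 between batches of the same donor and 0.958 between donors.

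Over 24 relations of the ribosomal protein score, the clearest was with the receptor score: with group means removed, r = -0.567 (permutation p = 0.00053, adjusted p = 0.0127) and Spearman rho -0.552 (permutation p = 0.00125, adjusted p = 0.03), and r = -0.404 without the 2 farthest mice. Within groups r was -0.689 (human, permutation p = 0.00496, adjusted p = 0.0397), -0.739 (squirrel monkey, exact permutation p = 0.0305, adjusted p = 0.105) and -0.436 (macaque, permutation p = 0.157, adjusted p = 0.343), and within batches -0.533 (B, exact permutation p = 0.178) and -0.397 (F, exact permutation p = 0.356). With log2 library total r was -0.284 (permutation p = 0.116, adjusted p = 0.278; Spearman rho -0.379, permutation p = 0.0334, adjusted p = 0.137; r = -0.165 without the 2 farthest mice) and within groups -0.0505 (human), -0.238 (squirrel monkey) and -0.654 (macaque, permutation p = 0.0211, adjusted p = 0.101). Within batches it was -0.798 (B, exact permutation p = 0.018, adjusted p = 0.101) and -0.758 (F, exact permutation p = 0.0425, adjusted p = 0.127). With library total as a covariate the mean difference of the ribosomal list was 0.28 in the combined comparison, from 0.27.

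With the library number, which follows the plate, r was -0.102 (permutation p = 0.58, adjusted p = 0.819; Spearman rho -0.0785, permutation p = 0.666, adjusted p = 0.761; r = -0.0917 without the 2 farthest mice), and within groups 0.0533 (human), -0.642 (squirrel monkey, exact permutation p = 0.0879, adjusted p = 0.234); Spearman rho was 0.147 in macaque mice, and r within batches was -0.506 (B) and 0.0521 (F). With the number in the sample title r was 0.395 (permutation p = 0.0253, adjusted p = 0.101; Spearman rho 0.299, permutation p = 0.0951, adjusted p = 0.21; r = 0.548 without the 2 farthest mice). Within groups it was -0.112 (human), 0.881 (squirrel monkey, exact permutation p = 0.00476, adjusted p = 0.0397; Spearman rho 0.667, exact permutation p = 0.0831) and -0.0118 (macaque), and within batches 0.14 (B) and -0.374 (F). In squirrel monkey mice all title numbers of batch C exceed those of batch D, so the relation there is not separate from the difference between these batches.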
